A study of Drosophila melanogaster and Drosophila yakuba and Drosophila virilis with 6 samples.

How the data were processed

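Expression was measured with Illumina tag profiling, in which transcripts are cut with the restriction enzyme NlaIII and a short tag beside a site is sequenced and counted. The samples were eye-antennal and wing imaginal discs of wandering larvae of the last instar of D. melanogaster (CantonS strain), D. yakuba and D. virilis, with 1 library for each of the 6 combinations. The deposited files hold counts: per the file headers each line gives the counts of tags at 1 genomic position with the gene that the authors assigned to it. The values are whole numbers whose totals differ between libraries, so they were read as raw counts. Bowtie 0.12.1 is listed in the submitters' processing notes. The builds behind all coordinates, the number of mismatches and the handling of tags with several matches are not given in the sources used here. For D. yakuba and D. virilis each library has 2 files, a gene mapping, used throughout, and a genome mapping of the same library that places positions on D. melanogaster genes, used as an alternative. Over positions in both files with a gene in each, the 2 mappings gave the same D. melanogaster gene at 90.5% and 90.7% of positions in D. yakuba and 87.9% and 89.7% in D. virilis (eye-antennal and wing).

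The counts were summed to 1 value per gene and library. The files hold no strand column, so all tags assigned to a gene were summed, whatever their strand. The sum of sense tags foreseen in the design could not be formed. Genes were paired between species by the D. melanogaster gene that the gene mapping files give for each position, which left 7807 paired genes. Of 13646 D. melanogaster gene identifiers, 12504 (91.6%) had a symbol in the reference used. The others are given by identifier only and could not be counted in the gene lists described below. Gene positions come from the BDGP6.54 annotation (release 115) by gene identifier, which covers 38 of the 40 genes called across species, and no coordinate of the files was converted.

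Library totals ran from 1860370 to 5673047 tags. A count of 0 allows up to 3 tags, and folds against 0 were computed against 3 tags. Libraries within a species were scaled by TMM factors, 1.05 and 0.949 in D. melanogaster, 1.02 and 0.980 in D. yakuba and 1.09 and 0.918 in D. virilis (eye-antennal and wing). Genes with at least 10 tags over both libraries of a species were compared. The fold is the ratio of tags per scaled library size with an exact conditional binomial (Clopper-Pearson) 95% interval, and log2 folds were computed with 0.5 tags added to each count. A mean log2 fold across species that includes a count of 0 is given as a bound, with 3 tags in place of that 0, or a log2 fold of 0 where the other disc had at most 3 tags. A gene was counted as higher in a disc when the bound nearer 1 was at least 2-fold. Each group has 1 library, so no test within a species was made.

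Across species, edgeR quasi-likelihood tests (glmQLFit and glmQLFTest) were fitted to the 6 libraries with species as a block and the disc as the tested term, leaving 2 residual degrees of freedom. Genes were filtered with filterByExpr (minimum count 10), which left 5953 genes, and p-values are two-sided and adjusted by Benjamini-Hochberg with a threshold of 0.05. The species serves as the replicate in this test.

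The 27 fixed gene lists, 629 matched members in all with 16 symbols unmatched, were written before the data were examined. They cover retinal determination, photoreceptor and ommatidial specification, neuronal differentiation, phototransduction, EGFR signalling, antennal identity, retinal glia, wing and notum patterning, wing disc myoblasts, trachea, Hox and homeotic genes, Notch signalling, Hedgehog, Dpp and Wg signalling, JAK/STAT signalling, cell cycle, ecdysone response, cuticle and apical matrix, fat body, salivary gland, hemocytes, larval muscle, brain and neuroblasts, heat shock and stress, reference genes, cytosolic and mitochondrial ribosomal proteins, and proteasome. Some genes stand in more than 1 list. Within a species each list was described by its counts, its median log2 fold and the percentile of that median among 10000 random lists matched on expression in 20 bins. Across species lists with at least 3 tested members were tested with limma camera (preset correlation 0.01 and estimated correlation) and fry. A further 2 lists, ring gland (9 genes) and midgut and peritrophic matrix (23 genes), were written after the genes with the largest folds had been seen.

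Genes were named by a rule set before the data were examined. Within a species these were the 12 genes in each direction with the largest conservative fold among genes with at least 50 tags, and across species up to 12 genes in each direction with the largest mean log2 fold among those past the threshold with the same sign in 3 of 3 species. From each list up to 4 members with the most tags and up to 4 with the largest conservative fold could be named, and reference genes were always eligible. Other called genes and list members past the threshold over the list alone were named after their values had been seen.

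Alternatives fixed before the data were examined were total gene tags or DESeq2 size factors for scaling, no filter or at least 50 tags, the most abundant tag of each gene, leaving out positions with 1 tag, thinning the deeper library to the total of the shallower one, the genome mapping, DESeq2, limma-voom, RLE factors, no species block, no filter on low counts, and leaving out each species. Added after the data had been seen were the pairing by the genome mapping and leaving out positions with 1 tag in the test across species, and leaving out each species, the genome mapping and the reading of the estimated correlation and fry as alternatives for the lists.

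The procedures were tested on simulated data. With 4-fold differences put into 200 genes of at least 100 tags the rule for folds recovered 99.5%, 98.5% and 100% of them in libraries like those of the 3 species (D. melanogaster, D. yakuba, D. virilis), with 1, 1 and 0 false calls. With 8-fold and 32-fold differences put into genes of at least 50 tags the edgeR test recovered 100% of 100 genes each, with 4 false calls among 5805 genes. The simulated libraries within a species held counting error only. In the data not every gene with folds over 8 passed the edgeR test. The gene oc, at least 29.4-fold, 8.96-fold and 28.6-fold higher in the eye-antennal libraries (D. melanogaster, D. yakuba, D. virilis), had an edgeR adjusted p of 0.0603. The recovery thus holds for the simulated settings only. Computations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.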

Results

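Transcripts of eye-antennal and wing imaginal discs, the larval epithelia that form the adult eye and antenna and the adult wing and notum, were counted by sequencing tags next to NlaIII sites. Discs came from wandering larvae of the last instar of D. melanogaster (CantonS), D. yakuba and D. virilis, with 1 library for each of the 2 discs in each of the 3 species, 6 libraries in all. The D. melanogaster libraries held 2207612 tags (eye-antennal) and 1860370 tags (wing). Those of D. yakuba held 5673047 and 2200615 tags, and those of D. virilis 2065918 and 3132492 tags, in the same order. There were no replicates within a species and disc, so a difference within a species had no replicate check and carries no p-value. Folds within a species are given with exact conditional binomial (Clopper-Pearson) 95% intervals in brackets, which cover counting error only. A fold against 0 tags is a lower bound computed against 3 tags per library. It lies above the interval bound by which genes were counted, as with 314-fold against 255-fold for CG13560 in D. melanogaster. A gene was counted as higher in a disc when the interval bound nearer 1 was at least 2-fold.

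Tags at positions assigned to no gene made up 2.04% (exact 95% interval 2.02 to 2.05) of the D. melanogaster eye-antennal library and 0.886% (0.873 to 0.900) of its wing library. The shares were 2.29% (2.28 to 2.30) and 2.05% (2.03 to 2.07) in D. yakuba and 3.09% (3.07 to 3.12) and 1.24% (1.23 to 1.25) in D. virilis. These tags lay at 17334 positions in the eye-antennal and 1927 in the wing library of D. melanogaster, at 3611 and 1735 in D. yakuba, and at 29479 and 4920 in D. virilis. Genes with at least 1 tag numbered 12292 and 9661 in D. melanogaster, 10473 and 9415 in D. yakuba, and 13156 and 10725 in D. virilis. Odorant, gustatory and ionotropic receptor genes with a tag numbered 132 in the eye-antennal and 26 in the wing library of D. melanogaster, 38 and 26 in D. yakuba, and 94 and 36 in D. virilis.

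The first comparison asked which genes differed between the discs of D. melanogaster. In the eye-antennal library gl, a zinc finger factor of photoreceptor development, was 565-fold (101 to 22333) higher, and the Pax6 homologue toy was 285-fold (50.8 to 11272) higher. The neuronal genes Appl and scrt were 103-fold (46.9 to 280.3) and 167-fold (29.7 to 6636) higher. CG13560 was at least 314-fold, CG13285 at least 158-fold, CG14400 at least 80.0-fold and CG14075 at least 34.8-fold higher. CG32032, CG32986 and a gene listed only as FBgn0085406 were 85.4-fold (33.1 to 315), 113-fold (30.9 to 936) and at least 45.3-fold higher. The ecdysteroid synthesis gene spok, expressed in the ring gland, was at least 86.2-fold higher. In a ring gland list written after these genes had been seen, 5 of 8 measured genes were higher in the eye-antennal library and 0 in the wing library, with phtm 14.7-fold (7.59 to 32.8), sad 19.4-fold (8.73 to 53.8), jhamt at least 29.9-fold and Akh 14.6-fold (2.32 to 606) higher.

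In the wing library of D. melanogaster the Jonah protease gene Jon66Ci was at least 78.2-fold higher, and the cuticle protein genes Cpr64Aa and Lcp3 were at least 53.4-fold and 190.3-fold (33.6 to 7567) higher. The ornithine aminotransferase gene Oat was 250.3-fold (44.4 to 9936) and CG14963 296-fold (52.6 to 11738) higher. Obp56d, CG6959, CG2116 and CG42834 were 57.4-fold (31.8 to 116), 56.5-fold (33.4 to 104), 50.8-fold (27.3 to 107) and 63.9-fold (24.6 to 237) higher. The mucin gene Muc11A was at least 29.1-fold and sordd2 at least 32.2-fold higher. The salivary glue gene Sgs5 was 30.1-fold (23.6 to 38.9) higher. In a midgut and peritrophic matrix list, also written after the top genes had been seen, 4 of 9 measured genes were higher in the wing library and 0 in the eye-antennal library.

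Of the fixed lists in D. melanogaster, 6 of 8 retinal determination genes were higher in the eye-antennal library, among them eya 21.1-fold (17.7 to 25.4), so 11.4-fold (7.27 to 19.0) and ey 82.9-fold (14.6 to 3303), and toe was 1 of the 2 not counted. Of 21 photoreceptor and ommatidial genes 14 were higher there, with lz at least 31.7-fold and oc at least 29.4-fold, and of 14 neuronal differentiation genes 9 were, with CadN 8.62-fold (5.76 to 13.4) and nrv3 34.7-fold (14.6 to 108). Antennal identity genes were higher in 6 of 12 cases, with dan at least 29.7-fold and ato 65.2-fold (11.4 to 2606). Of 33 wing and notum patterning genes 7 were higher in the wing library, with Dr 15.2-fold (10.1 to 23.9) and nub 17.5-fold (9.74 to 34.6), and 4 in the eye-antennal library, with TfAP-2 11.8-fold (6.25 to 25.1) and H15 27.6-fold (4.65 to 1121). Of 10 wing disc myoblast genes 2 were higher in the wing library, zfh1 3.39-fold (2.42 to 4.84) and Him 29.5-fold (9.69 to 147).

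Markers of other larval tissues differed between the D. melanogaster libraries as well, and the labels do not say whether brain, ring gland or fat body was cleared from the discs of any species. Of 10 brain and neuroblast genes 7 were higher in the eye-antennal library, with nerfin-1 44.5-fold (14.98 to 218), Ilp2 at least 11.5-fold and Hug at least 8.95-fold, and larval muscle genes were higher there in 6 of 13 cases, with Mlc2 3.10-fold (2.83 to 3.39) and bt 29.9-fold (8.01 to 251). Of 13 fat body genes 6 were higher in the wing library, with Fbp1 7.44-fold (7.10 to 7.80), while Lsp2 was 1.29-fold (1.26 to 1.31) higher there and was not counted. Of 12 salivary gland genes 5 were higher in the wing library, with Sgs3 17.2-fold (15.03 to 19.9), and so were 4 of 14 hemocyte genes, with SPARC 4.42-fold (3.87 to 5.06), while 1 hemocyte gene, lz, was higher in the eye-antennal library. In D. yakuba 2 of 13 hemocyte genes were higher in the eye-antennal and 0 in the wing library. Of 77 cytosolic ribosomal protein genes 18 were higher in the wing and 4 in the eye-antennal library. The largest folds were those of RpL14, 29.6-fold (27.3 to 32.2) higher in the eye-antennal library, and RpLP2, 19.7-fold (18.4 to 21.1) higher in the wing library, and each of these rested on 1 tag position, RpL14 with 22264 and 545 tags there and RpLP2 with 0 and 12901 (eye-antennal and wing). The reference genes Gapdh1, alphaTub84B and Prx2 were 2.94-fold (2.61 to 3.32), 2.35-fold (2.26 to 2.45) and 3.97-fold (2.998 to 5.31) higher in the wing library.

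Of 8134 genes with at least 10 tags over both D. melanogaster libraries, 648 were higher in the eye-antennal and 553 in the wing library. Scaling by total gene tags in place of TMM factors shifted every log2 fold by 0.15 and gave 778 and 436 genes. With at least 50 tags the counts were 323 in the eye-antennal and 447 in the wing library, so that the larger count was on the wing side.

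The same question in D. yakuba gave ring gland genes among the largest folds in the eye-antennal library: phtm, spok, dib and sad, all genes of ecdysteroid synthesis, were 201-fold (68.6 to 974.6), 367-fold (65.8 to 14518), at least 26.2-fold and 23.4-fold (17.1 to 32.9) higher. Of 7 measured genes of the ring gland list 6 were higher there, phtm, spok, dib and sad among them. The list was written after genes with the largest folds had been seen, so this count is not separate from those genes. Akh was 1.57-fold (1.12 to 2.18) higher in the wing library and was not counted. The proneural gene ato was 24.6-fold (17.5 to 35.9) higher and the ARID factor gene retn 31.4-fold (19.5 to 54.1). The lectin gene Lectin-galC1 was 248-fold (106 to 764) and superdeath 33.4-fold (19.4 to 62.8) higher. CG9150, CG9021, CG13227 and CG7714 were 44.9-fold (24.3 to 93.9), 86.6-fold (23.8 to 717), 129-fold (23.0 to 5114) and 55.4-fold (18.8 to 269) higher.

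In the wing library of D. yakuba the POU factor gene pdm2 was at least 84.0-fold and the homeobox gene Dr 22.2-fold (16.0 to 31.7) higher. CG15406, mat and a gene listed only as FBgn0068441 were 756-fold (135 to 29952), 629.7-fold (112 to 24977) and 595-fold (106 to 23601) higher. CG4382, CG10514, CG18095 and the phosphatase gene Alp8 were 189-fold (128 to 293), at least 124-fold, at least 48.2-fold and 163-fold (44.3 to 1365) higher. Cpr64Aa was 193-fold (33.5 to 7725) and FBgn0236786, paired with FBgn0000099 of D. melanogaster, 26.8-fold (20.9 to 34.7) higher. CG11878 was at least 84.9-fold higher in the gene mapping, whereas the genome mapping of the same libraries gave it a log2 fold of 1.33, towards the eye-antennal disc.

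Of the fixed lists in D. yakuba, 5 of 8 retinal determination genes were higher in the eye-antennal library, with eya 12.4-fold (11.03 to 13.9) and ey 33.7-fold (14.3 to 104), and so were 10 of 20 photoreceptor and ommatidial genes, with lz 17.8-fold (10.5 to 32.7) and ro 17.9-fold (6.01 to 87.9). Neuronal differentiation genes were higher there in 4 of 11 cases, with Appl 9.07-fold (7.11 to 11.8), and Notch signalling genes in 5 of 15, with E(spl)mgamma-HLH 10.9-fold (7.40 to 16.8). Of 28 wing and notum patterning genes 7 were higher in the wing library and 0 in the eye-antennal library, with nub at least 37.5-fold and Antp 25.8-fold (14.5 to 49.7). Of 12 fat body genes 8 were higher in the wing library, with Lsp1beta 16.9-fold (15.6 to 18.3) and Lsp1gamma 11.3-fold (10.99 to 11.7). Larval muscle genes had a median log2 fold of 1.41, with 1 of 11 counted as higher in the eye-antennal library, and 2 of 7 midgut genes were higher there. Of 7 brain and neuroblast genes nerfin-1 was 9.42-fold (3.57 to 35.3) higher in the eye-antennal library and ple, the tyrosine hydroxylase gene, 6.536-fold (4.50 to 9.64) higher in the wing library. No gene of the 65 cytosolic ribosomal protein genes, and none of the 8 reference genes, was counted as higher in either disc.

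Of 8118 genes measured in D. yakuba, 297 were higher in the eye-antennal and 284 in the wing library. With at least 50 tags the counts were 264 in the eye-antennal and 164 in the wing library.

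In D. virilis the eye-antennal library had higher levels of the retinal genes gl at least 94.1-fold, toy 239-fold (65.8 to 1984) and ey at least 77.6-fold, of scrt 167-fold (56.9 to 815), and of danr, a gene of antennal development, 455-fold (81.2 to 18038). The rhomboid protease gene ru was at least 112-fold and twit at least 333-fold higher. The peptide hormone genes Dsk and Akh were 199.7-fold (54.8 to 1657) and at least 68.1-fold higher. CG12911, FBgn0204906 and FBgn0197927, the last paired with FBgn0000313 of D. melanogaster, were 85.8-fold (47.6 to 173), 628-fold (112 to 24873) and at least 65.1-fold higher. Of 4 measured genes of the ring gland list Akh was counted as higher, and dib, with 1.18-fold (0.992 to 1.40), was not.

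In the wing library of D. virilis the largest folds included genes of gut and peritrophic matrix: PGRP-SC2 at least 530.3-fold, Muc18B at least 277-fold, Peritrophin-15a 857-fold (153 to 33878) and the trypsin gene epsilonTry 389.9-fold (152 to 1432). Of 7 measured genes of the midgut list 6 were higher in this library, PGRP-SC2, Muc18B, Peritrophin-15a and epsilonTry among them. The list was written after genes with the largest folds had been seen, so this count is not separate from those genes. The storage protein gene Lsp1gamma was 85.2-fold (72.4 to 101) and the odorant-binding protein gene Obp99b 73.3-fold (61.6 to 87.8) higher. CG10911, CG3868 and CG8952 were at least 127-fold, 188-fold (80.3 to 579.5) and 146-fold (56.7 to 537) higher. Genes listed only as FBgn0199685, FBgn0199071 and FBgn0199686 were at least 482-fold, 677-fold (121 to 26774) and at least 66.1-fold higher.

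Of the fixed lists in D. virilis, 6 of 8 retinal determination genes were higher in the eye-antennal library, with eya 28.0-fold (23.5 to 33.5), and so were 15 of 19 photoreceptor and ommatidial genes, with sev 33.8-fold (11.2 to 168), and 7 of 11 neuronal differentiation genes, with nSyb 15.7-fold (8.51 to 32.3). Of 13 brain and neuroblast genes 11 were higher there, with Gad1 at least 19.1-fold and Hug at least 17.3-fold. Of 28 wing and notum patterning genes 12 were higher in the wing library and 0 in the eye-antennal library, with Antp 38.6-fold (17.5 to 106), vg 27.9-fold (10.7 to 104) and Ser 3.30-fold (2.86 to 3.82). Of 11 fat body genes 5 were higher in the wing library, with Lsp2 40.02-fold (33.5 to 48.3). Larval muscle genes were higher in the wing library in 5 of 9 cases, with Mlc2 3.66-fold (3.37 to 3.98) and Tm2 6.28-fold (4.96 to 8.05), where D. melanogaster had 6 of 13 higher in the eye-antennal library. The reference genes Gapdh1 and alphaTub84B were 1.03-fold (0.995 to 1.07) and 1.02-fold (1.01 to 1.04) higher in the wing library, and both turned to the eye-antennal side under total-tag scaling.

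Of 8864 genes measured in D. virilis, 599 were higher in the eye-antennal and 412 in the wing library. Total-tag scaling shifted every log2 fold by 0.25 and gave 711 and 311 genes. With at least 50 tags the counts were 221 in the eye-antennal and 348 in the wing library, so that the larger count was on the wing side. The genome mapping gave 353 and 317, but it left 31.3% and 27.4% of tags without a gene, against 3.09% and 1.24% in the gene mapping. Genes with at least 10 tags in a library numbered 5470 and 5736, against 7649 and 7523 (eye-antennal and wing). Fewer genes could thus be counted.

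The comparison across species asked which disc differences exceeded their spread between the 3 species, with each species giving 1 library of each disc. Log2 folds of the eye-antennal over the wing disc are given as mean ± SD (n = 3 species) with 0.5 tags added to each count. Where a disc had 0 tags in a species the mean is a bound against 3 tags, given as at least or lower and without SD. The Pax6 homologues ey and toy rose in the eye-antennal disc by at least 5.67 and 6.29 ± 2.22, and the retinal determination genes eya, so and Optix by 4.27 ± 0.60, 2.82 ± 0.72 and 2.09 ± 0.51. Factors and receptors of photoreceptor and cone cell development followed with at least 4.75 for lz, at least 3.91 for sev, 3.33 ± 0.08 for phyl and 3.11 ± 0.63 for the Bar homeobox gene B-H2. The neuronal genes scrt, Appl, nerfin-1 and Nrt had 6.30 ± 1.204, 5.22 ± 1.80, at least 4.04 and 2.23 ± 0.19. Brain tissue, not stated to have been cleared, would also carry transcripts of these 4 genes. The dopamine transporter gene DAT had at least 3.30. The values of ru, danr, retn and SP2353 were at least 5.52, 6.11 ± 2.09, at least 4.63 and at least 4.54, and those of FBgn0000313 and superdeath at least 4.59 and 5.01 ± 0.86. The matrix metalloprotease gene Mmp2 had 3.99 ± 0.75 and CG31676 4.10 ± 0.22. The Notch target genes E(spl)mgamma-HLH and E(spl)mdelta-HLH had 3.56 ± 1.33 and 1.84 ± 0.17.

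In the wing disc Sox15, a Sox family factor, had -6.01 or lower, and the homeobox gene Dr and the wing selector gene vg had -4.35 ± 0.41 and -4.05 ± 1.02. The POU factor genes nub and vvl had -4.29 or lower and -3.59 ± 1.17. FBgn0000099 had -4.92 ± 0.65, and the cuticle and mucin genes Cpr12A and Muc55B had -4.08 ± 1.47 and -2.84 or lower, with 1 and 3 tags of Cpr12A and 0 and 3 of Muc55B in D. yakuba (eye-antennal and wing). Fbp1, a gene of the fat body list, a tissue not stated to have been cleared from the discs, had -3.50 ± 0.67. CG16758 and E(spl)m6-BFM had -2.76 ± 0.63 and -2.36 ± 0.41.

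These genes were among those past the threshold in an edgeR quasi-likelihood test with the species as a block, adjusted by Benjamini-Hochberg over 5953 genes. It called 40 genes at an adjusted p under 0.05, 29 higher in the eye-antennal and 11 in the wing disc. With 0.5 tags added each had the same sign in 3 of 3 species, but 14 had 0 tags in a disc of some species and 4, CG7299, Cpr12A, E(spl)m6-BFM and Muc55B, had under 10 tags in a species. The signs of Muc55B and CG7299 in D. yakuba are undetermined when a count of 0 allows up to 3 tags. There CG7299 had 7 and 0 tags (eye-antennal and wing), and the eye-antennal library was deeper. Cpr12A had 1 and 3 tags in D. yakuba and E(spl)m6-BFM 2 and 7 in D. melanogaster, in the same order. These are too few to settle either sign. The smallest adjusted p, 0.00722, was shared by eya (2L, 6527447 to 6546976 in BDGP6.54), Sox15 (2R, 14201390 to 14212413), Dr (3R, 29556386 to 29565244), scrt (3L, 3983896 to 3994003), superdeath, CG31676 and FBgn0000099, with mean log2 folds between -6.01 or lower and 6.30 and 3 of 3 species in the same direction. The edgeR adjusted p was 0.0229 for ey, with a mean log2 fold of at least 5.67 in 3 of 3 species, and 0.0103 for Mmp2, with 3.99 in 3 of 3 species. For 16 genes, Appl, sev, ru and nub among them, the adjusted p was at least 0.0497. With 2 residual degrees of freedom the count moved with the settings: edgeR with RLE size factors called 24 genes, the most abundant tag of each gene gave 9, leaving out positions with 1 tag gave 15, and leaving out D. melanogaster, D. yakuba or D. virilis gave 61, 32 and 130. DESeq2 called 205 genes, limma-voom 44, edgeR without a filter on low counts 104, and edgeR without the species block 0, where 128 genes had an unadjusted p under 0.05.

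**Figure D1:**
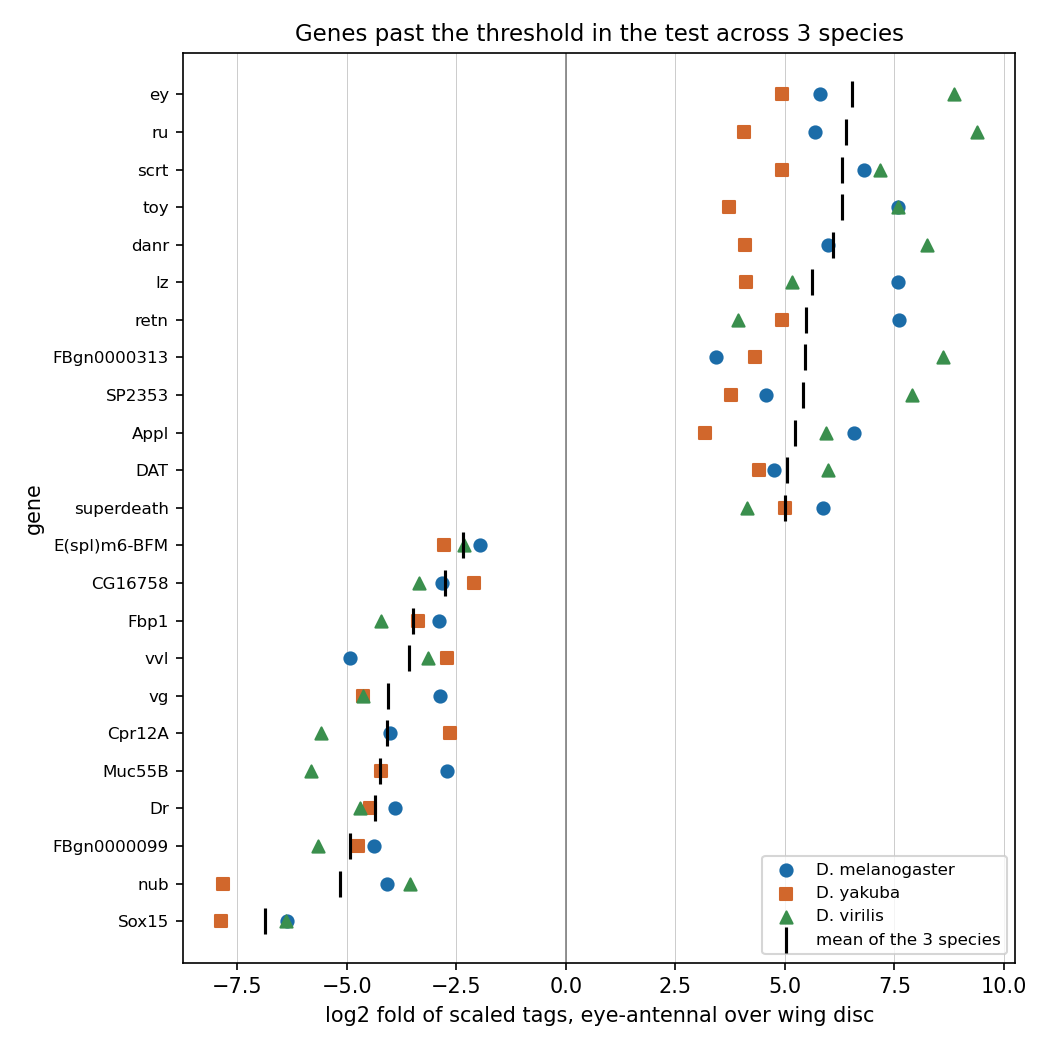
Log2 fold of scaled tags, eye-antennal over wing disc (x axis), of the 23 genes named by the rule (y axis); points are the 3 species, with 0.5 tags added to each count, and the bar is their mean. So drawn, all 23 genes lie on the same side of 0 in 3 of 3 species, from a mean of 6.53 for ey to -6.87 for Sox15, and points with 0 tags in a disc depend on the 0.5 added.

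Gene lists fixed before the data were examined were tested across species with limma camera at a preset correlation of 0.01, and again with an estimated correlation. Camera ranks a list against the other genes and does not test whether its genes changed. The correlation was estimated from a fit with 2 residual degrees of freedom. For Notch signalling genes the estimate (-0.063) was below the preset value, yet the unadjusted camera p rose from 1.0e-05 to 0.042. A list that fails with an estimated correlation is therefore not shown by this alone to hold correlated genes. Retinal determination genes ranked towards the eye-antennal disc (camera adjusted p = 5.6e-09), with 5 of 8 past the edgeR threshold over all genes tested and 6 adjusted over the list alone. With an estimated correlation the list had adjusted p = 0.310. Photoreceptor and ommatidial genes ranked towards it (camera adjusted p = 1.7e-09; adjusted p = 0.316 with an estimated correlation), 5 of 16 over all genes and 12 adjusted over the list alone, boss at least 2.77 and oc at least 4.17 among the latter. Neuronal differentiation genes ranked towards it (camera adjusted p = 2.6e-07; adjusted p = 0.310 with an estimated correlation), with Appl alone over all genes and 5 of 9 adjusted over the list alone, elav 1.80 ± 0.88 and CadN 2.45 ± 1.18 among them. Antennal identity genes ranked towards it (camera adjusted p = 4.4e-04; adjusted p = 0.310 with an estimated correlation), with danr over all genes and, adjusted over the list alone, 6 of 10 higher in the eye-antennal disc and al (-0.87 ± 0.21) in the wing disc. EGFR signalling genes ranked towards it (camera adjusted p = 0.0215; adjusted p = 0.374 with an estimated correlation), with ru over all genes and 3 of 13, ru, rho and pnt, adjusted over the list alone. Without D. yakuba the EGFR list had a camera adjusted p of 0.112. Its median log2 fold was -0.13 in D. melanogaster, on the wing side, 0.69 in D. yakuba and 0.18 in D. virilis.

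Notch signalling genes ranked towards the eye-antennal disc (camera adjusted p = 4.2e-05; adjusted p = 0.310 with an estimated correlation), with E(spl)mdelta-HLH and E(spl)mgamma-HLH over all genes. Adjusted over the list alone 7 of 14 were higher there, neur 1.66 ± 0.47 and E(spl)m4-BFM 1.81 ± 0.86 among them, and Ser (-1.58 ± 0.38) was higher in the wing disc. This was the 1 list past the threshold with the directional test of fry (adjusted p = 0.0479). That test asks whether the genes of a list move, on balance, one way and does not compare them with other genes. The mixed test of fry, which ignores direction, passed the threshold for other lists too, such as cell cycle genes (fry mixed adjusted p = 0.00276). Wing and notum patterning genes ranked towards the wing disc (camera adjusted p = 5.6e-09; adjusted p = 0.310 with an estimated correlation), with nub, Dr and vg over all genes and 11 of 26 adjusted over the list alone, Antp -3.89 ± 1.76, tsh -1.67 ± 0.71 and caup -1.15 ± 0.16 among them. Fat body genes ranked towards the wing disc (camera adjusted p = 7.0e-06; adjusted p = 0.310 with an estimated correlation), with Fbp1 over all genes and, adjusted over the list alone, 6 of 10 higher in the wing disc and Lip4 (1.26 ± 1.23) in the eye-antennal disc.

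Cytosolic ribosomal protein genes ranked towards the wing disc with a median of the mean log2 folds of -0.31 (fry adjusted p = 0.135; camera adjusted p = 0.00200; adjusted p = 0.316 with an estimated correlation), and 0 of 53 passed over all genes by edgeR or adjusted over the list alone. Proteasome genes ranked towards it with -0.34 (fry adjusted p = 0.512; camera adjusted p = 0.0439; adjusted p = 0.466 with an estimated correlation), 0 of 27 passed either way, and without D. melanogaster the camera adjusted p was 0.691. The proteasome medians were -0.01 in D. yakuba and -0.11 in D. virilis. Under total-tag scaling the proteasome medians of D. yakuba and D. virilis turned to the eye-antennal side.

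The other lists did not pass the camera threshold. Retinal glia genes had an adjusted p of 0.0514, with 4 of 9 higher in the eye-antennal disc adjusted over the list alone, moody 2.19 ± 1.06 and loco 1.72 ± 0.65 among them, and vkg (-1.65 ± 0.96) in the wing disc. Phototransduction genes had 0.0788, with inaC (at least 3.59) of 7 genes adjusted over the list alone. Brain and neuroblast genes had 0.127, with nerfin-1 over all genes and nerfin-1 and pros of 4 adjusted over the list alone. Wing disc myoblast genes had 0.988, with Him (-3.42 ± 1.55) in the wing disc and ct and kirre in the eye-antennal disc adjusted over the list alone. Trachea genes had 0.344, with vvl over all genes and, adjusted over the list alone, vvl in the wing disc and pnt and obst-A in the eye-antennal disc. Hox and homeotic genes had 0.588, and adjusted over the list alone Dfd (at least 3.35) was higher in the eye-antennal disc and Antp in the wing disc. Hemocyte genes had 0.393, with lz over all genes, lz and gcm in the eye-antennal disc and vkg and ush in the wing disc adjusted over the list alone. Cell cycle genes had 0.393, with stg (1.12 ± 0.17) and dap (1.33 ± 0.10) in the eye-antennal disc and RnrL (-1.197 ± 0.34) in the wing disc adjusted over the list alone.

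Ecdysone response genes had a camera adjusted p of 0.344, with ImpL2 (1.43 ± 0.62) adjusted over the list alone, and larval muscle genes had 0.457, with bt (3.32 ± 1.13) adjusted over the list alone. No gene passed over all genes or adjusted over the list alone among the Hedgehog, Dpp and Wg (0.988), cuticle and apical matrix (0.212), heat shock (0.0751), mitochondrial ribosomal protein (0.142) and reference genes (0.210). The median and the mean of the fitted log2 folds differed in sign for hemocytes (-0.18 and 0.25) and wing disc myoblasts (-0.04 and 0.03), and camera and fry pointed to opposite discs for the Hedgehog, Dpp and Wg list. Salivary gland and JAK/STAT genes had too few members in this test. Their median log2 folds were -1.76 (12 genes) and 0.44 (5) for salivary gland in D. melanogaster and D. yakuba, and 0.37, 0.30 and 0.34 for JAK/STAT in D. melanogaster, D. yakuba and D. virilis. Larval muscle passed the camera threshold without D. virilis (adjusted p = 3.1e-06), and so did phototransduction (0.00163), hemocytes (0.0412), brain (0.00199) and retinal glia (0.0176) without D. yakuba, trachea (0.0458) and cuticle (0.0127) without D. melanogaster, and reference genes (0.0233) without D. virilis, all at the preset correlation. With an estimated correlation, which was read only over 3 species, none of these lists passed (larval muscle adjusted p = 0.783, brain 0.565).

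**Figure D2:**
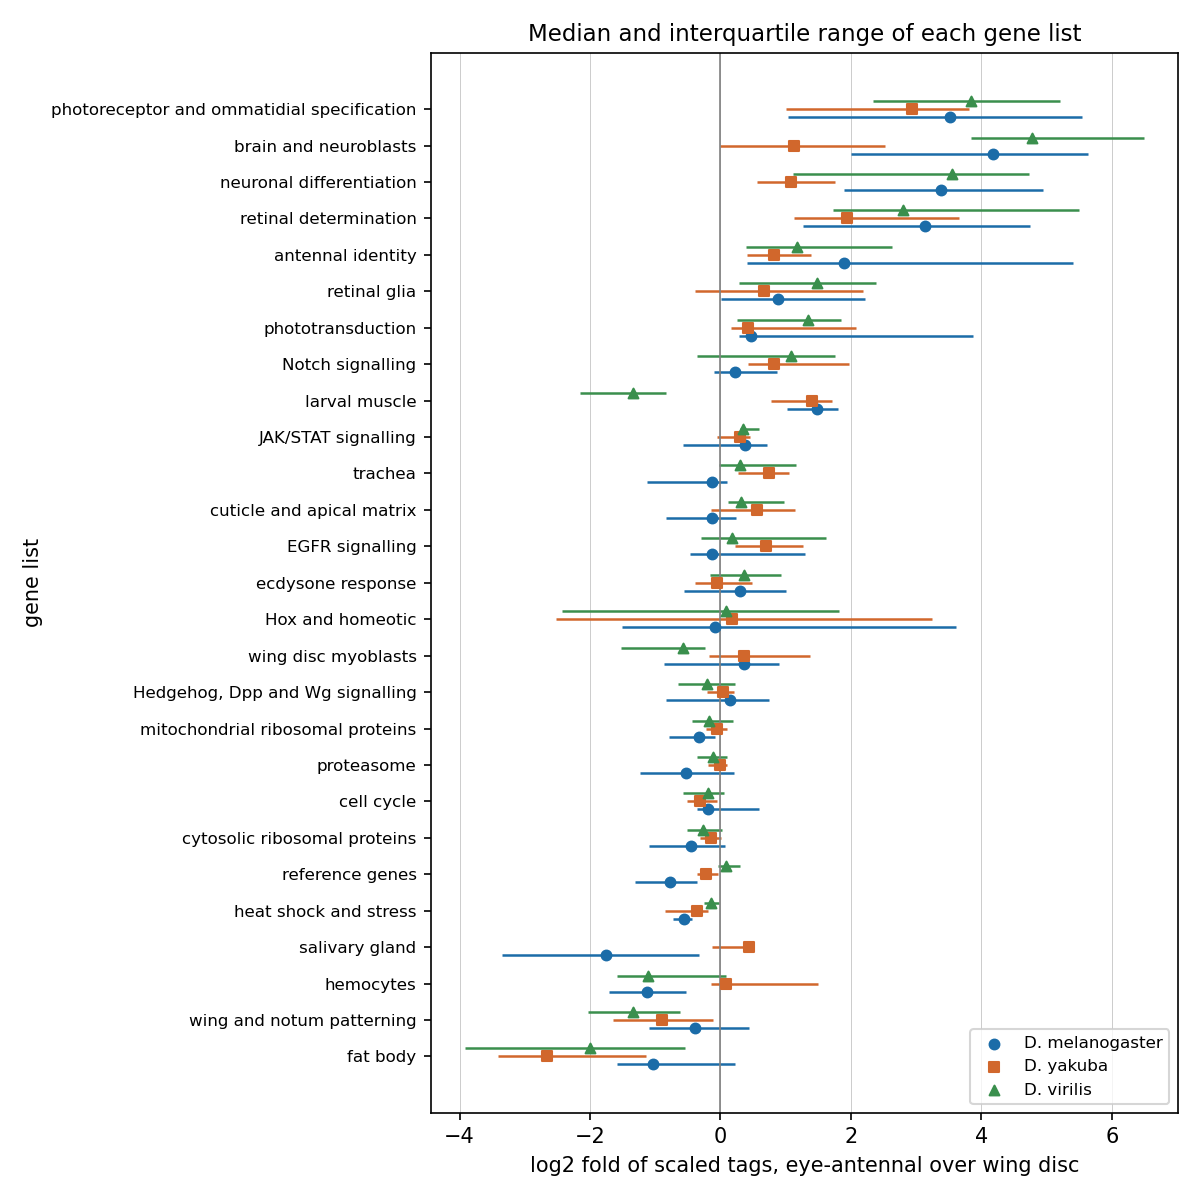
Median (points) and interquartile range (lines) of the log2 fold of scaled tags, eye-antennal over wing disc (x axis), of the gene lists with at least 3 measured genes (y axis) in each of the 3 species. Photoreceptor genes have medians of 3.52, 2.93 and 3.84 and fat body genes of -1.03, -2.66 and -2.005 in D. melanogaster, D. yakuba and D. virilis, and the medians nearest 0 turn sign in places under total-tag scaling.

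Disc folds were compared between species across genes, which are not independent replicates. Pearson's r of the log2 folds was 0.416 (Spearman's rho 0.294) over 6409 genes of D. melanogaster and D. yakuba, 0.454 (0.252) over 6314 genes of D. melanogaster and D. virilis, and 0.371 (0.219) over 6156 genes of D. yakuba and D. virilis. Of 5571 genes measured in all 3 species, 60 were counted as higher in the eye-antennal and 22 in the wing library in each, where independent calls would give 0.394 and 0.274. Counted as higher in opposite discs were 20 genes between D. melanogaster and D. yakuba, 16 between D. melanogaster and D. virilis, and 18 between D. yakuba and D. virilis, 33 different genes. Among them ple, Mlc2, Tm2, ara and epsilonTry stood in the lists or among the named genes.

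Over 7807 paired genes the nearest library to each of the 6 was the other disc of its own species. Correlations between species also depend on the pairing of genes and on the tag sites of each species, an effect that was not measured. They therefore do not show that expression differed more by species than by disc. Spearman's correlation across genes between the 2 discs was 0.886 in D. melanogaster, 0.944 in D. yakuba and 0.900 in D. virilis. Between eye-antennal libraries it was 0.666 for D. melanogaster and D. yakuba, 0.576 for D. melanogaster and D. virilis, and 0.616 for D. yakuba and D. virilis, and between wing libraries 0.724, 0.644 and 0.632.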

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

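Of the tests in this part, those of depth, of the fat body, of the summed neuropeptide genes and of the retinal genes were chosen after the results they bear on had been seen, while those of the receptor genes, of the 4 ring gland genes and of the splits were set before, and the bounds for depth, for the fat body, for the summed neuropeptide genes and for the retinal genes were reworded after their values had been seen.

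Positions outside genes drew attention as data that no comparison used. Their share of tags was 2.04% and 0.886% in the eye-antennal and wing libraries of D. melanogaster, 2.29% and 2.05% in D. yakuba, and 3.09% and 1.24% in D. virilis. Thinned to equal depth, the eye-antennal library of D. melanogaster still had 7.79 times as many such positions, against 1.16 in D. yakuba, and in D. virilis the eye-antennal library had more of them (29479 against 4920) while being the shallower one, which argues against greater depth as the cause. Odorant, gustatory and ionotropic receptor genes with a tag numbered 127 against 26 in D. melanogaster at equal depth, a ratio of 4.88, and the ratio was 2.98 in D. virilis, while D. yakuba had 26 such genes in each library, but the tags in these genes numbered 1009 and 325 in D. melanogaster, 2037 and 642 in D. yakuba and 1184 and 1498 in D. virilis (eye-antennal and wing, at own depth). A candidate explanation for the D. melanogaster eye-antennal library is background tags spread over the genome, which the tags of D. virilis leave less clear there, and the tissue itself stays open as an untested explanation, since the antennal disc forms an olfactory organ.

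Of the fat body genes 6 of 13 in D. melanogaster, 8 of 12 in D. yakuba and 5 of 11 in D. virilis were higher in the wing library and 0 in the eye-antennal library. The 6 most abundant fat body genes differed in fold between each other by 8.66 times in D. melanogaster, 3.06 times in D. yakuba and 74.8 times in D. virilis, but by 3.50, 1.71 and 7.90 times without Fbp1, Lsp1alpha and Cpr. With single libraries and counting error as the only spread, one fat body source carried into both libraries in different amounts cannot be told apart from several. Fat body carried over with the wing discs, tested as all 6 genes being higher in the wing library, held in 1 species, D. yakuba, while Fbp2 was lower in the wing library of D. melanogaster (0.860 times) and Cpr was 1.14 times as high (0.895 to 1.45) in that of D. virilis. That test asks for the pattern itself, so fat body carried over with the wing discs cannot be told apart from a difference between the discs, which was not tested.

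Retinal genes were higher in the eye-antennal libraries of 3 species, ring gland genes in those of D. melanogaster and D. yakuba, and neuropeptide genes in those of D. melanogaster and D. virilis. The ring gland genes nvd, sro, ouib and jhamt, found by symbol and summed, were 7.79-fold (4.40 to 15.02) higher in D. melanogaster. There jhamt gave 117 of the 132 eye-antennal tags and sro went the other way with 6 against 12. The sum was 18.7-fold (7.92 to 58.2) higher in D. yakuba, where ouib and jhamt alone were found. In D. melanogaster nvd was not found. A gene without a symbol or a pair would be missed, so absence does not show that it had no tags. Ring gland tissue in these 2 libraries is a candidate source, while D. virilis had 5 tags against 0. The neuropeptide genes Ilp2, Ilp3, Ilp5, Dh44 and Hug, summed, were at least 24.8-fold higher in D. melanogaster, 1.99-fold (0.570 to 10.7) in D. yakuba on 16 and 3 tags, and 167-fold (29.4 to 6629) in D. virilis, and whether brain tissue is their source in all 3 species cannot be told apart at the D. yakuba counts. The retinal determination and photoreceptor genes had a median D. yakuba over D. melanogaster ratio of 0.926 (quartiles 0.659 to 1.69, 26 genes) in the eye-antennal libraries. The neuropeptide genes had 0.0665 (0.0365 to 0.113), so the retinal genes did not follow them between these 2 species. The brain list genes nerfin-1, ple and dpn had 0.234, 0.375 and 3.51. Of these dpn alone lay above the retinal quartiles. It was 2.93-fold higher in the wing library of D. melanogaster and 1.65-fold higher in the eye-antennal library of D. yakuba, counted in neither. With such mixed brain list genes, brain tissue as the source of the retinal genes cannot be told apart without a measure of its share. The disc itself remains an untested explanation for each of these groups.

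For the 40 genes called across species, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many genes, the real one, and the highest other split gave 0. Of the 10, 4 keep the discs of each species apart as the species block does. With 10 splits a share under 0.05 is out of reach.

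Some genes were counted in opposite discs in different species, and medians of larval muscle and of several other lists had opposite signs, differences that were not tested. The log2 fold of ara was 1.71 in D. melanogaster and -2.73 in D. virilis. For ple it was 3.29, -2.70 and 4.77 in D. melanogaster, D. yakuba and D. virilis, and for epsilonTry -4.44, 4.09 and -8.44. The D. virilis value of ple rests on 10 and 0 tags, with 0.5 added to each. Mlc2 had 1.63 and -1.87, and Tm2 1.80 and -2.64, in D. melanogaster and D. virilis. The larval muscle list had medians of 1.47, 1.41 and -1.34 in D. melanogaster, D. yakuba and D. virilis.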

How the results depend on the processing

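Of the alternatives here, pairing by the genome mapping, positions with 1 tag left out across species, and all but total-tag scaling and at least 50 tags for the lists were chosen after the data had been seen. The planned comparison of sense tags with the sum of sense and antisense tags was not run, because the files hold no strand column. All values rest on every tag assigned to a gene. The cause was not tested for any change given here. A filter of at least 50 tags, which leaves fewer genes, gave 323 and 447 genes in D. melanogaster, 264 and 164 in D. yakuba and 221 and 348 in D. virilis (eye-antennal and wing). In D. melanogaster and D. virilis the larger count thus changed from the eye-antennal to the wing side. The genome mapping gave 353 and 317 in D. virilis, where it left 31.3% and 27.4% of tags without a gene, so fewer genes could be counted. Scaling by total gene tags gave 778 and 436 genes in D. melanogaster and 711 and 311 in D. virilis (eye-antennal and wing), against 648 and 553 and 599 and 412. The 40 genes across species (29 eye-antennal, 11 wing) became 205 (136 and 69) with DESeq2, 24 (17 and 7) with RLE factors, 104 (82 and 22) without a filter on low counts, 9 (5 and 4) with the most abundant tag and 15 (8 and 7) without positions of 1 tag. Pairing by the genome mapping gave 35, with 6 in the wing disc, and limma-voom 44. Of the 40 genes, DESeq2 and the run without a filter shared 40, limma-voom 30, RLE 24, the genome pairing 21, positions of 1 tag left out 14 and the most abundant tag 8. Without the species block edgeR called 0 genes (0 eye-antennal and 0 wing), with 128 at an unadjusted p under 0.05. Leaving out a species gave 32 to 130 genes, 24 to 97 in the eye-antennal and 8 to 33 in the wing disc. Camera called 10 lists, 0 with an estimated correlation, 9 with total-tag scaling, 11 with at least 50 tags and 11 to 13 without a species. The directional test of fry called 1. With at least 50 tags Pearson's r of the folds was 0.464 for D. melanogaster and D. yakuba, 0.383 for D. melanogaster and D. virilis and 0.419 for D. yakuba and D. virilis. The log2 fold of CG11878 in D. yakuba turned to 1.33 with the genome mapping. Of 3618 values of single genes in a species under alternatives, 3279 stayed within their counting interval, 338 moved beyond it and 1, of a gene counted as higher in a disc, reversed. Sign changes of genes not counted, such as Gapdh1 and alphaTub84B of D. virilis under total-tag scaling, are among the others. A filter on tags does not enter the fold of a gene. The 483 values without a filter and the 448 with at least 50 tags therefore could not move, and both are counted in the 3279. Of 246 values of the 23 genes named across species by the rule 160 stayed past the threshold and 86 kept their direction without passing it.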

Other observations

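The test of tags outside the most abundant position was chosen after 3 of the ribosomal protein genes had been seen.

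Some genes were counted as higher in the same disc in each of the 3 species without passing the edgeR threshold across species, and those named here were chosen after their values were seen. The acetylcholinesterase gene Ace was 6.14-fold, 3.92-fold and 8.67-fold higher in the eye-antennal library (D. melanogaster, D. yakuba, D. virilis; adjusted p 0.105), and the zinc finger gene peb was 4.77-fold, 8.49-fold and 11.3-fold (0.0528). The gluconeogenic gene Pepck1 was 4.33-fold, 8.12-fold and 3.16-fold higher in the wing library (0.0592), and the odorant-binding protein gene Obp99b 3.21-fold, 11.2-fold and 73.3-fold (0.172). The GATA factor gene grn was 5.30-fold, 5.43-fold and 4.15-fold higher in the wing library (0.0528).

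Ribosomal protein genes called higher in either disc library of D. melanogaster numbered 22, against 0 in D. yakuba and 4 in D. virilis. For the 20 of them with at least 20 tags outside their most abundant position, the median log2 fold in the direction of the gene was 1.55, and that of the tags outside this position was 0.83. Those tags reached 2-fold in 9 of the 20 genes and went the other way in 3, RpL35A, RpLP2 and RpS6. Of the other called genes with as many tags outside, 59.0% reached 2-fold in D. melanogaster, 83.3% in D. yakuba and 72.1% in D. virilis. The 4 called ribosomal protein genes of D. virilis had a median of -0.19 outside, with 2 in the same direction and 1 at 2-fold. As a hypothesis, tag positions gained or lost in 1 library may account for part of these calls, RpL14, RpL28, RpL35A and RpLP2 in particular. RpL28 had 0 and 100 tags at its most abundant position and 15 and 12 outside it (eye-antennal and wing). The hypothesis does not account for the 9 genes whose other tags also reached 2-fold. The median of 0.83 lay close to the bound of 1 set for this test, and a difference between the discs stays open as untested.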
